A study of Mus musculus with 2 samples.

How the data were processed

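The data were the authors' peak lists for GRCm38 (mm10): a list for each replicate, a pooled list and a replicated list. Per the notes deposited with the files, each replicate's list was derived from that replicate's alignments and a further file, the pooled list from both replicates' alignments, and the replicated list from the pooled list and both replicates' lists. The deposited lists give for each peak a fold enrichment (a ratio over background, on a linear scale) and the −log10 of its p value and of its q value, as the authors' peak caller wrote them. The notes do not define the fold column, which was read as a ratio because the lists are in narrowPeak format and its values are all above 1. The smallest −log10 p was about 2 in each list, so p of about 0.01 was the authors' calling threshold, and 80.2% of peaks in replicate 1 and 82.7% in replicate 2 also had q of 0.01 or less. The aligner, the peak caller, their versions, the control and the read depth are not given in the sources used here. Alignments and signal tracks were not analysed here. Fold enrichment was compared only within a list, never between lists.

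Tests on the files showed that all 83170 replicated peaks are identical to peaks of the pooled list and make up 47.2% of its peaks and 82.0% of its covered sequence. Of the replicated peaks, 79.9% were overlapped by a peak of both replicates, 12.3% by a peak of replicate 1 only, 6.89% by a peak of replicate 2 only and 0.889% by neither, so the authors' rule for a replicated peak was not overlap of the 2 replicates' lists alone.

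Genes were the 21755 protein-coding genes of GENCODE M21 on chromosomes 1 to 19 and X, and a gene's TSS was its annotated start. A gene counted as marked if a replicated peak lay within 1 kb of the TSS. A gene's fold enrichment was that of the strongest peak overlapping this window, and a peak has a single value over its whole length. Breadth was the share of the 5 kb either side of the TSS covered by peaks. A promoter was CpG-rich if the 500 bp either side of the TSS had a GC share of at least 0.55 and an observed to expected CpG ratio of at least 0.6. Domains were replicated peaks joined across gaps of at most 3 kb. Overlap between replicates meant at least 50% of a peak's own length. Random overlap came from 1000 circular shifts of the peaks along each chromosome, with a fixed seed, and from 200 in the alternatives and for peaks found in a single replicate.

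The comparisons, their tests, the alternatives of the sensitivity part, the lists of genes and the rule for naming genes were chosen before the data were examined, except where a choice is said to have come after. The 18 lists, 470 gene symbols plus the olfactory receptors by symbol pattern, were Hox genes, forebrain progenitor TFs, regional forebrain TFs, neurogenic TFs, midbrain, hindbrain and spinal cord TFs, mesoderm, heart and muscle TFs, endoderm TFs, neural crest TFs, blood and endothelial genes, secreted signalling ligands, mature neuron genes, glial genes, housekeeping genes, cell cycle genes, Polycomb and trithorax subunits, germline and pluripotency genes, imprinted genes and olfactory receptor genes. The rule named the Hox genes as a group, genes with a TSS in the 20 domains with the most covered sequence, the 2 members of each list with the largest and the 2 with the smallest breadth, a fixed set of developmental and control genes from Foxg1 to Gapdh, and the 5 genes per replicate with the highest fold among those marked in that replicate only.

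Lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, and by rotating list membership along the gene order, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. Progenitor TFs were compared with 5 other TF lists by Fisher's exact test and by a permutation test with 100000 resamples, adjusted over 10 comparisons. Differences in mean log2 enrichment were adjusted over 5 comparisons. Intervals are exact binomial (Clopper-Pearson) at 95%.

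In a self-test, marks were simulated in short runs of neighbouring genes, and the olfactory receptor list was left out. Fisher's test called 6.12% and the rotation 3.18% of 850 lists without a difference. With planted odds ratios of 2, 5 and 15, Fisher's test called 38%, 97% and 100% of 400 lists each, made of genes drawn at random. The Hoxa domain in the data held 14 protein-coding TSSs, so the self-test was milder than the data for clustered lists. The overlap measure found 40.3% of peaks shared where 40% of 20000 peaks had been copied. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and pysam 0.24.0, samtools 1.23.1 and bedtools 2.31.1.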

Results

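H3K27me3, the histone mark of Polycomb-repressed chromatin, was mapped by ChIP-seq in the forebrain of mouse embryos (strain B6NCrl) at embryonic day 10.5, a stage at which most forebrain cells are dividing neural progenitors. The series held a single group of 2 biological replicates. Each replicate was a pool of male and female embryos, 69 in replicate 1 and 51 in replicate 2, and was processed with a ChIP protocol for small samples. No other tissue, stage, genotype or treatment was in the series, so the comparisons were between the replicates and between groups of genes within the tissue.

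The authors' peak lists held 155093 peaks in replicate 1 and 132648 in replicate 2, a mean of 143870 ± 15871 (SD, n = 2). These covered 104 Mb and 96.9 Mb of the autosomes and the X chromosome. The set that the authors call replicated held 83170 peaks over 110.3 Mb, or 4.19% of those chromosomes, with a median width of 657 bp and a median enrichment of 3.11-fold over background. Gene-level values below are from this replicated set unless a replicate is named, and each gene was scored by its transcription start site (TSS), the annotated start of the gene. Peak lists hold no read counts, so the sequencing depth of the replicates is unknown, and binomial intervals cover counting of genes only.

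The 39 Hox genes, which give cells their position along the trunk and hindbrain and lie outside the forebrain's own programme, all carried H3K27me3 at the TSS. On average 99.9% of the 5 kb either side of a Hox TSS was covered by peaks. Peaks covered 100% of the Hoxa cluster (6:52155590-52260880, GRCm38) and of the Hoxc cluster (15:102921103-103036852), and 99.6% of the Hoxd cluster (2:74668310-74765142). In the Hoxb cluster (11:96194316-96368256) they covered 88.5%, with 85.9 ± 0.289% (SD, n = 2) in the replicates' own lists. The strongest peak at a Hox TSS was in the Hoxb cluster, at 31.8-fold enrichment, against 29.6-fold in Hoxa, 26.4-fold in Hoxc and 25.3-fold in Hoxd.

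**Figure D1:**
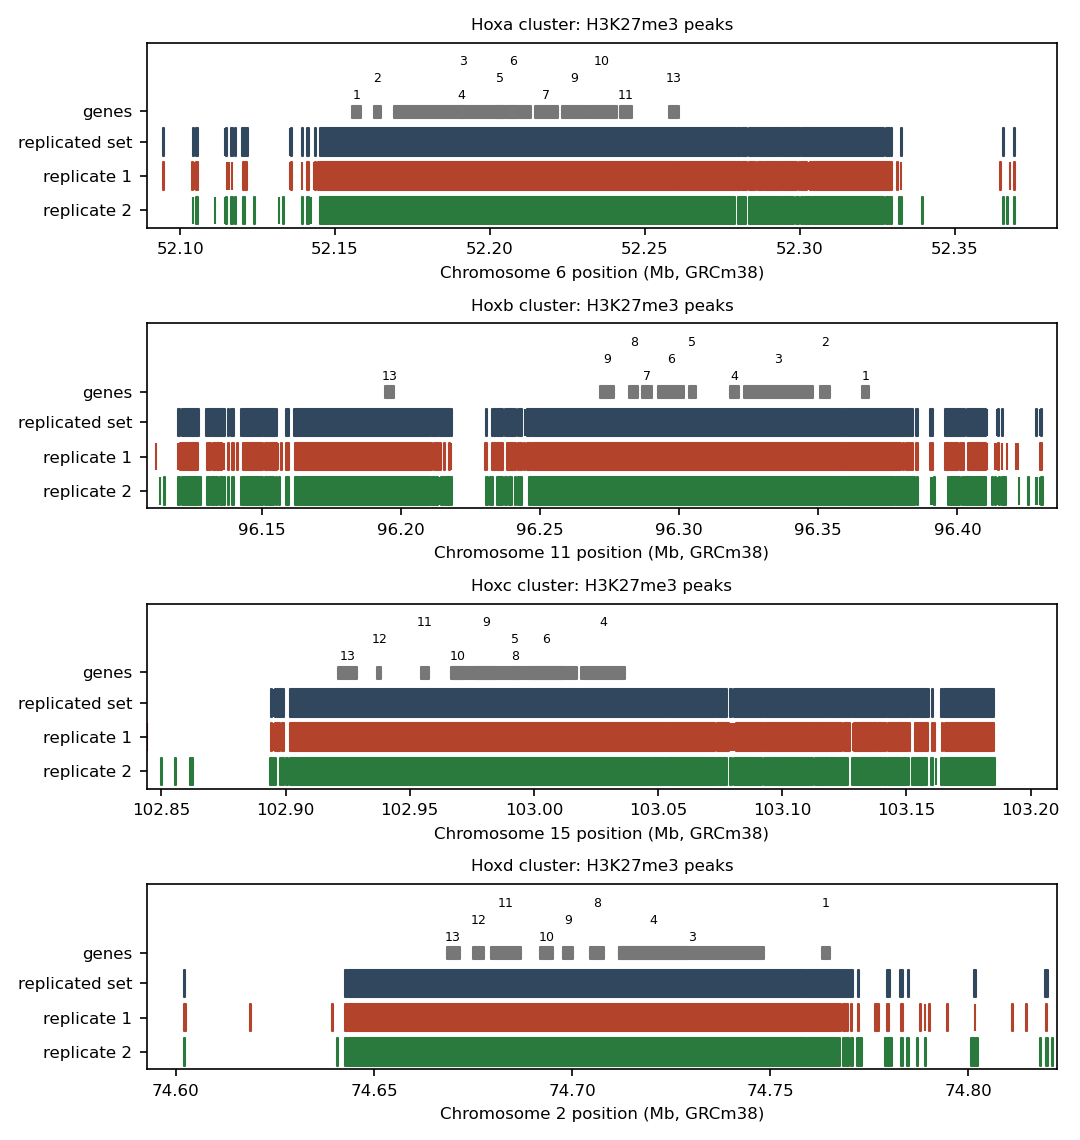
Maps of the 4 Hox clusters, with chromosome position in Mb (GRCm38) on the horizontal axis, and bars for the peaks of the replicated set and of each replicate under the Hox genes (grey, labelled by number). Peaks cover 100% of Hoxa and Hoxc, 99.6% of Hoxd and 88.5% of Hoxb.

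The same mark lay on developmental regulators of nearly every lineage tested, including those of the forebrain. Among 21755 protein-coding genes, 6418 had a replicated peak within 1 kb of the TSS (29.5%, 95% exact binomial interval 28.9 to 30.1%), and this is the rate against which the lists were set. With the TSS base alone the number was 3811. All 30 midbrain, hindbrain and spinal cord transcription factors (TFs) were marked, as were all 28 regional forebrain TFs and all 10 neural crest TFs. Of the mesoderm, heart and muscle TFs, 44 of 46 were marked, the exceptions being Myog and Tbx6, and of the endoderm TFs 13 of 14, the exception being Hnf4a. Among neurogenic TFs 22 of 25 were marked, without St18, Myt1 and Neurod4, and among forebrain progenitor TFs 27 of 32, without Bcl11a, Sox11, Gli3, Hes1 and Tcf7l2. Secreted signalling ligands of the Wnt, Fgf, Bmp and Hedgehog kinds were marked in 43 of 45 cases, without Fgf20 and Bmp5. Exceptions and other members of short counts were picked out after their values were seen.

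Fisher's exact test (two-sided) of each list against all other protein-coding genes, adjusted over the 18 lists, gave 1.34e-20 for the Hox genes and for the mesoderm, heart and muscle TFs and 3.27e-20 for the ligands. Adjusted p was 4.27e-16 for the midbrain, hindbrain and spinal cord TFs, 4.12e-15 for the regional forebrain TFs and 4e-10 for the forebrain progenitor TFs. It was 3.61e-09 for the neurogenic TFs, 2.33e-06 for the endoderm TFs and 8.13e-06 for the neural crest TFs. Genes are not independent replicates, and neighbours such as the Hox genes share domains. Rotating list membership along the gene order kept all of these lists past the threshold (permutation test, largest adjusted p = 0.000301).

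Individual regulators showed how broad the marking was. At Foxg1 (gene at 12:49382660-49386861), the TF that specifies the telencephalon, the strongest TSS peak had 10.6-fold enrichment, and peaks covered 98.4% of the 5 kb either side (95.5 ± 2.04% in the replicates, SD, n = 2). At Pax6 (gene at 2:105668900-105697364), needed for dorsal forebrain and eye, peaks covered all of this window, and the strongest TSS peak had 11.6-fold enrichment. Sox2 (gene at 3:34650405-34652461), expressed in neural progenitors, was covered over 73.8% of the window at 5.20-fold, and here the replicates lay far apart (54.9 ± 30.2%, SD, n = 2). Otx2, which marks the anterior brain, was covered over 88.3% at 8.36-fold. Nkx2-1 and Gsx2, both in the list of regional forebrain TFs, were covered over the whole window at 17.0-fold and 12.4-fold. Barhl1, a TF of the caudal forebrain, had 34.2-fold. Among regulators of other lineages, enrichment was 28.7-fold at T (early mesoderm), 20.5-fold at Myod1 (skeletal muscle) and 19.2-fold at Gata4 (heart and gut). It was 14.4-fold at Pax3 (dorsal neural tube and crest) and 13.98-fold at Sox17 (endoderm). These values lay above those of Foxg1, Pax6, Sox2 and Otx2 and within the range of Nkx2-1, Gsx2 and Barhl1. The strongest TSS peak had 22.1-fold enrichment at Shh, 18.4-fold at Fgf8 and 6.37-fold at Wnt8b.

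Neuronal effector genes were also marked in this tissue, in which most cells are not yet neurons. Of 42 mature neuron genes, 37 had a TSS peak (88.1%, adjusted p = 9.14e-15, Fisher's exact test), among them Gad2 at 13.0-fold and Slc32a1, the vesicular GABA transporter, at 25.4-fold. Gad1, Snap25, Vip, Tph2 and Gabrg2 had none. Glial genes were marked in 9 of 15 cases (60%, exact adjusted p = 0.0242), with peaks over the whole 5 kb either side of Olig1. Blood and endothelial genes, marked in 10 of 23 cases (43.5%), did not differ from other genes (exact adjusted p = 0.190), although peaks covered the whole 5 kb either side of Tal1, Fli1 and Flt1. With the TSS base alone, or among CpG-rich promoters, this list did pass (exact adjusted p = 0.00461 and 0.0275), but only 4 of its genes have such a promoter.

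Genes of general cell function were mostly free of the mark. Housekeeping genes were marked in 4 of 36 cases (11.1%, exact adjusted p = 0.0233), namely B2m, Ldha, Pgk1 and Reep5, and neither Actb nor Gapdh had a replicated peak within 5 kb of the TSS (Actb had a 2.61-fold peak in replicate 2's own list, covering 1.95% of that window). With the TSS base alone the housekeeping difference was no longer past the threshold (8.33%, exact adjusted p = 0.226). Olfactory receptor genes, used by sensory neurons of the nose, had almost no replicated peaks at the TSS, with 3 of 1093 marked (0.274%). The marked ones were Olfr94, Olfr95 and Olfr1342. Fisher's exact test, which counts neighbouring receptors as independent, gave an adjusted p of 3.24e-163. Rotating list membership along the gene order gave an adjusted p of 0.000165 (permutation test). None of the 1093 has a CpG-rich promoter. Cell cycle genes were marked in 2 of 19 cases, Ccnd1 and Ccne1 (10.5%, exact adjusted p = 0.0956). This list passed with a window of 2.5 kb either side (exact adjusted p = 0.0402) and with the authors' pooled peaks (adjusted p = 0.0375).

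Polycomb and trithorax subunits, which lay down, read or oppose the mark, did not differ detectably from other genes, with 7 of 26 marked (26.9%, exact adjusted p = 1), and the Polycomb chromobox gene Cbx4 had 26.4-fold enrichment. Germline and pluripotency genes were marked in 4 of 18 cases (22.2%, exact adjusted p = 0.648), namely Nanog, Pou5f1, Tdrd1 and Tdrkh. Both lists rose above the rate of other genes under some settings without passing the threshold, as with pooled peaks (34.6% and 38.9%). Imprinted genes were marked in 12 of 22 cases (54.5%, exact adjusted p = 0.0233), including Grb10 and Dlk1. This call was lost when list membership was rotated along the gene order (permutation test, adjusted p = 0.0730) and without either replicate (50% in both cases).

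**Figure D2:**
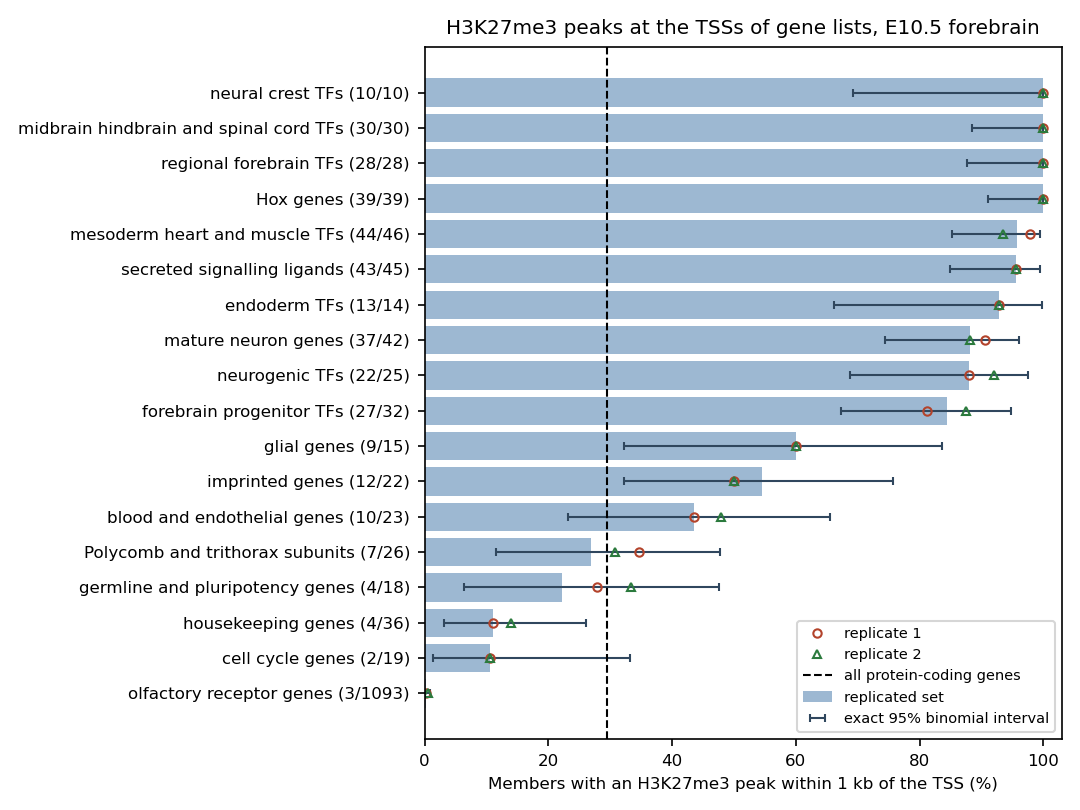
Percentage of each fixed gene list with a replicated H3K27me3 peak within 1 kb of the TSS, as bars with 95% exact binomial intervals, points for each replicate's own peaks, and a dashed line at the rate of all protein-coding genes (29.5%). The Hox, regional forebrain, midbrain to spinal cord and neural crest lists stand at 100%, and olfactory receptors at 0.274%.

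By mean breadth, forebrain progenitor TFs carried less H3K27me3 than regional forebrain TFs and midbrain, hindbrain and spinal cord TFs, though most were marked. Peaks covered 76.0% of the 5 kb either side of a progenitor TF's TSS on average, against 98.2% for regional forebrain TFs, 94.6% for midbrain, hindbrain and spinal cord TFs and 99.9% for Hox genes. The medians lay closer, at 93.97% for progenitor TFs and 100% for each of these other lists. At least 95% was covered at 16 of 32 progenitor TFs and 25 of 28 regional forebrain TFs. For midbrain, hindbrain and spinal cord TFs it was 23 of 30. The progenitor mean was lowered by little-covered members such as Sox11 and Gli3, both at 0%. The difference in means from regional forebrain TFs was -22.2 percentage points (permutation test, two-sided, adjusted p = 0.00075, family of 10 comparisons). From midbrain, hindbrain and spinal cord TFs it was -18.5 points (permutation adjusted p = 0.00777). From Hox genes it was -23.9 points, on every measure used here a description rather than a test. The 39 Hox genes lie in 4 marked clusters and are not independent. Neighbouring regional forebrain TFs such as Dlx1 and Dlx2 may not be either, yet the permutation counts them as independent. Its p value against that list may therefore overstate the evidence. Against neurogenic TFs (80.3%) and mesoderm, heart and muscle TFs (81.1%) no difference was detected, at -4.27 and -5.09 points (permutation adjusted p = 0.692 and 0.617), and these signs turned with 10 kb either side (2.79 and 4.23 points). Without replicate 2 they were -9.51 and -10.3 points (permutation adjusted p = 0.315 and 0.219).

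By presence of a TSS peak, no list other than the Hox genes differed past the threshold from the progenitor TFs in the replicated set, although some did under other settings. The share of marked progenitor TFs (84.4%) was 15.6 points below that of Hox genes (-15.6, adjusted p = 0.0387, Fisher's exact test, which counts the clustered Hox genes as independent). This difference was not past the threshold with 2.5 kb either side (exact adjusted p = 0.401), with any protein-coding TSS of the gene (0.401), with pooled peaks (0.499) or without replicate 1 (0.0925). Against regional forebrain TFs and against midbrain, hindbrain and spinal cord TFs the difference was also -15.6 points (exact adjusted p = 0.0914 for both), and it passed in replicate 1 alone (-18.8, adjusted p = 0.0366) and with the TSS base alone (-28.1 and -24.8 points, adjusted p = 0.00591 and 0.0216). Peaks that both replicates overlapped, an alternative chosen after seeing the data, gave -21.9 points against both lists (exact adjusted p = 0.0196). Mesoderm, heart and muscle TFs differed by -11.3 points (exact adjusted p = 0.166), past the threshold with the TSS base alone (-19.4, adjusted p = 0.0400) and in replicate 1 alone (-16.6, adjusted p = 0.0341). Neurogenic TFs differed by -3.63 points (exact adjusted p = 1), which turned to 1.75 with pooled peaks.

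Enrichment of the strongest peak at marked TSSs was compared on the log2 scale, a measure added after seeing the data. Replicated peaks were up to 151 kb wide, and a gene within a long peak takes the value of that whole peak. Enrichment is therefore not independent of breadth, and these measures were not separated. Marked progenitor TFs had a mean log2 enrichment of 2.97 (SD 0.79 across 27 genes), against 4.77 for Hox genes, 4.03 for regional forebrain TFs and 4.17 for midbrain, hindbrain and spinal cord TFs. The differences of -1.79, -1.05 and -1.20 each had an adjusted p of 1.67e-05 over these 5 comparisons, from an unadjusted p of 1e-05, the smallest possible (permutation test). For the Hox genes this too is a description, since the permutation treats them as independent. All 11 Hoxa genes share a strongest peak of 29.6-fold and all 9 Hoxc genes of 26.4-fold. The permutation also counts neighbouring regional forebrain TFs as independent, so its p value against that list may overstate the evidence. Neurogenic TFs such as Neurog2 (15.6-fold) and Ascl1 (12.8-fold) had a mean of 3.67 (difference -0.70, permutation adjusted p = 0.00288), and mesoderm, heart and muscle TFs 3.70 (difference -0.73, adjusted p = 0.000687). In each replicate's own list all these differences had the same sign and an adjusted p of 0.00353 or less.

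**Figure D3:**
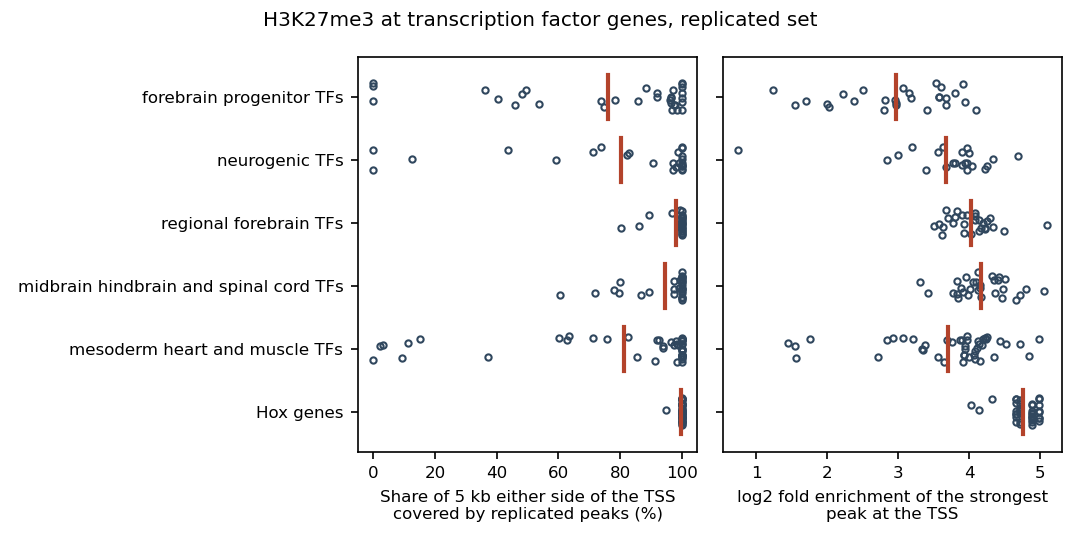
For 6 lists of TFs, each point is a gene, a vertical bar is the list's mean, and the horizontal axes give the percentage of the 5 kb either side of the TSS covered by replicated peaks and the log2 fold enrichment of the strongest TSS peak. Forebrain progenitor TFs average 76.0% covered, against 98.2% for regional forebrain TFs and 99.9% for Hox genes. The progenitor median is 93.97%, against 100% in both of those lists.

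CpG-rich promoters, the usual sites of Polycomb recruitment, were marked more often than others. A peak lay at 3093 of 8405 CpG-rich promoters (36.8%) and at 3325 of 13350 other promoters (24.9%), an odds ratio of 1.76 (Fisher's exact test, two-sided, p = 2.54e-77). With the TSS base alone the shares were 18.8% and 16.7%, an odds ratio of 1.16. By position, 5.02% of replicated peaks had their centre within 1 kb of a protein-coding TSS, against 1.56% after shifting the peaks along the chromosomes. Exons held 5.14% of peak centres (3.14% after shifts) and introns 38.1% (34.1% after shifts). Outside protein-coding genes lay 51.7%, fewer than the 61.2% after shifts. One-sided p was 0.001, the smallest that 1000 shifts can give, except for introns (0.00599), whose excess was lost on the autosomes alone (36.9%, permutation p = 0.368).

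Among chromosomes 1 to 19 and X, the X chromosome carried the densest marking. Replicated peaks covered 12.0% of it, with 10.6 ± 0.565% in the replicates' own lists (SD, n = 2), against 2.12 to 6.30% of the autosomes (median 3.41%), a ratio of 3.52. Chromosomes 11 (6.30%) and 19 (6.16%) came next. Of the X-linked protein-coding genes, 398 of 948 had a TSS peak (42.0%). Against the autosomes this was an odds ratio of 1.78 (Fisher's exact test, two-sided, p = 6.62e-17), a test added after seeing the data. It counts X-linked genes as independent although neighbours share domains, and no rotation was run, so this p may overstate the evidence. No test of the covered share was planned, as there is a single X.

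**Figure D4:**
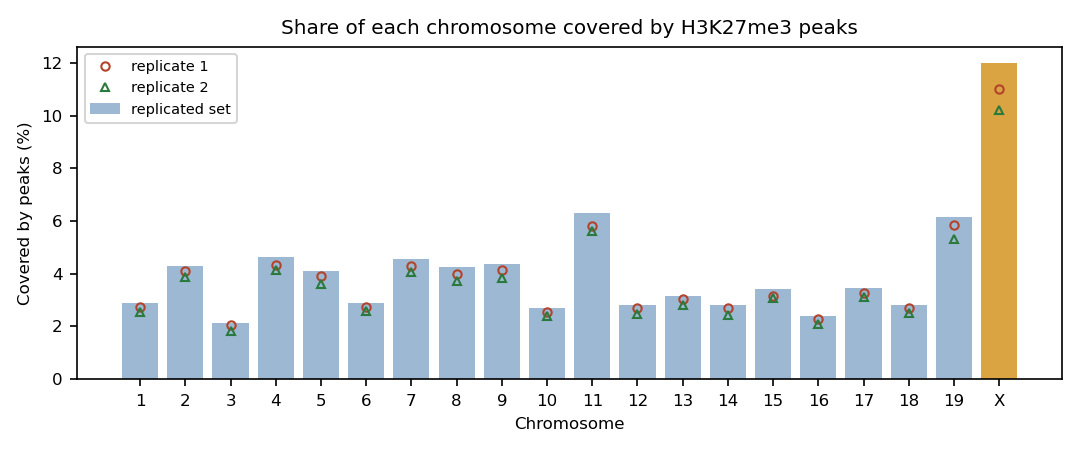
Percentage of each chromosome covered by H3K27me3 peaks, with bars for the replicated set and points for each replicate's own peaks. The X chromosome stands at 12.0%, above the autosomes' 2.12 to 6.30%.

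The domains with the most covered sequence were on X and at the Hoxc and Hoxa clusters. Joining replicated peaks across gaps of at most 3 kb gave 24642 domains, and the 3602 domains of 10 kb or more held 62.1% of the covered sequence. With gaps of at most 1 kb there were 38585 domains, and those of 10 kb or more held 43.4%. Of the 20 domains with the most covered sequence at gaps of at most 3 kb, 18 were on X, and 10 of the 20 were also in the top 20 at gaps of at most 1 kb. The largest, at X:99112778-99678400, contains the TSSs of Efnb1, an ephrin ligand that sets cell boundaries, and Pja1, and 544 kb of it was covered (526 ± 1.77 kb in the replicates, SD, n = 2). The next, at X:140329966-140893848, holds Frmpd3, Prps1, Tsc22d3, Mid2 and Tex13b, with 469 kb covered. Both autosomal ones were Hox clusters, namely Hoxc (15:102894081-103160682, 255 kb covered, 247 ± 1.46 kb in the replicates, SD, n = 2) and Hoxa with its neighbour Evx1 (6:52139201-52333076, 183 kb covered).

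The comparison of replicates asked how far the map repeats between embryo pools. Gene calls and single peaks were matched by different rules, so their shares cannot be set side by side. A TSS peak was found in both replicates for 6045 genes such as Foxg1, Pax6 and Barhl1, in replicate 1 only for 606, in replicate 2 only for 706, and in neither for 14398. That is the same call for 94.0% of genes, those marked in neither replicate included (Cohen's kappa 0.859, odds ratio 203). The share of marked genes was 30.6% in replicate 1 (6651 genes) and slightly higher in replicate 2 (6751 genes), a mean of 30.8 ± 0.325% (SD, n = 2). Of the genes marked in a single replicate, 409 from replicate 1 and 488 from replicate 2 were also outside the replicated set. The most enriched of these by fixed rule were Plxna2, Ptprj, Lrig3, Glp2r and Bex2 in replicate 1 (3.78-fold to 4.13-fold) and Wfs1, Coro1a, Sertad2, Tbkbp1 and Klf10 in replicate 2 (up to 5.4-fold), where Plxna2 encodes a semaphorin receptor and Klf10 a zinc finger TF.

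Single peaks were matched by the share of their own length. Of replicate 1's peaks, 43.5% were overlapped by a replicate 2 peak over at least 50% of their length, against a mean of 4.26% when peaks were shifted along the chromosomes. For replicate 2's peaks this was 50.9%, against 4.61%. By base pairs the Jaccard index was 56.6%, against 2.5%. All of these had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Counting any overlap of at least 1 bp raised the shares to 59.1% and 68.3%, and requiring a reciprocal overlap lowered them to 27.9% and 32.6%. The strongest 10% of peaks by fold enrichment were found again in 85.3% (replicate 1) and 91.9% (replicate 2) of cases, and the weakest 10% in 28.7% and 34.6%. The next weakest 10% were lowest, at 25.3% and 31.5%.

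**Figure D5:**
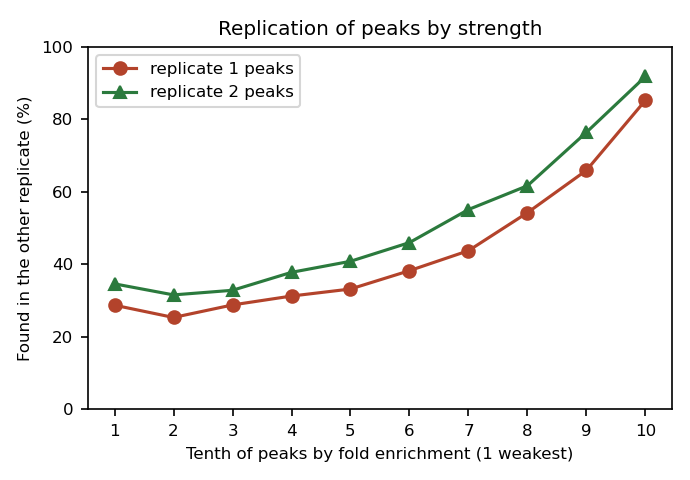
Percentage of each replicate's peaks found in the other replicate (vertical axis) by bin of fold enrichment, each holding 10% of the peaks (horizontal axis, 1 weakest), with a line per replicate. The share is lowest in the second weakest bin (25.3% in replicate 1, 31.5% in replicate 2) and highest in the strongest (85.3% and 91.9%).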

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

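Alternatives limited to the autosomes, those limited to peaks seen in both replicates and those on mean enrichment were chosen after seeing the data. Of 340 values of 48 results under alternatives, 302 kept direction and side of the threshold or, without a test, stayed within set limits. Of the rest, 12 newly passed the threshold, 13 no longer passed it, 10 changed direction and 3 without a test moved. The alternative with q of 0.01 or less kept 99.1% of replicated peaks, so it could change results on that set only a little. The lists of Hox genes, ligands, mature neuron genes, olfactory receptors and TFs of each lineage, the excess at CpG-rich promoters and the overlap of the replicates kept their direction and side under all alternatives run, though the odds ratio of CpG-rich promoters fell from 1.76 to 1.16 with the TSS base alone. Olfactory receptors had no value among CpG-rich promoters, since none has such a promoter. For the changes below the cause was not tested. Depth could not be assessed, since peak lists hold no read counts.

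With the TSS base alone, 3811 genes were marked, blood and endothelial genes passed (43.5%, exact adjusted p = 0.00461) and housekeeping genes did not (8.33%, 0.226), and progenitor TFs were marked less often than regional forebrain TFs (-28.1 points), midbrain, hindbrain and spinal cord TFs (-24.8) and mesoderm, heart and muscle TFs (-19.4). With 2.5 kb either side, cell cycle genes passed (10.5%, 0.0402), imprinted genes did not (54.5%, 0.0832), Polycomb and trithorax subunits turned to above other genes (38.5%), and the difference between progenitor TFs and Hox genes was no longer past the threshold (-9.38 points), as with any protein-coding TSS (-9.38), where germline and pluripotency genes turned (33.3%). With 10 kb either side, the breadth differences from neurogenic TFs (2.79 points) and mesoderm, heart and muscle TFs (4.23) changed sign.

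With pooled peaks, cell cycle genes passed (10.5%, 0.0375), imprinted genes did not (54.5%, 0.0830), Polycomb and trithorax subunits (34.6%) and germline and pluripotency genes (38.9%) turned, and progenitor TFs differed from Hox genes by -6.25 points and from neurogenic TFs by 1.75. With q of 0.01 or less the latter was 0.375 points. Among CpG-rich promoters alone, with fewer genes tested, blood and endothelial genes passed (100%, 0.0275), and glial (100%, 0.187) and imprinted genes (37.5%, 1) did not. The blood and endothelial list then held only 4 genes, all marked. The glial list held 2 genes, both marked, which is too few to pass. Rotation along the gene order left imprinted genes short of the threshold (54.5%, 0.0730). Peaks seen in both replicates gave -21.9 points between progenitor TFs and both regional forebrain TFs and midbrain, hindbrain and spinal cord TFs. On the autosomes alone the share of peaks in introns was 36.9%, no longer past the threshold. Gaps of at most 1 kb gave 38585 domains, those of 10 kb or more held 43.4% of the covered sequence in place of 62.1%, and 10 of the top 20 domains were shared with gaps of at most 3 kb (11 with gaps of at most 10 kb).

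Without either replicate, the other replicate's own peaks put Polycomb and trithorax subunits at 30.8 to 34.6%, germline and pluripotency genes at 27.8 to 33.3% and imprinted genes at 50% in both cases. Progenitor TFs then differed from Hox genes by -18.8 to -12.5 points, from regional forebrain TFs and from midbrain, hindbrain and spinal cord TFs by -18.8 to -12.5, and from mesoderm, heart and muscle TFs by -16.6 to -5.98. The breadth differences of progenitor TFs without a replicate were -9.51 to -5.34 points from neurogenic TFs and -10.3 to -5.03 from mesoderm, heart and muscle TFs. The ratio of X to the autosomes' median was 3.30 to 3.48.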

Other observations

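The tests of gene families by symbol and of promoter classes on X, the look at noncoding genes, and the test of whether peaks found in a single replicate are weak, were chosen only after the results were seen. Beyond the fixed lists, 269 families of at least 10 protein-coding genes sharing a symbol stem were compared with other genes (Fisher's exact test, adjusted over families). Of these, 44 were marked more often and 43 less often, and 28 and 13 also passed by rotation along the gene order. All 19 Wnt genes, of which 17 were also in the fixed lists, and all 14 Nkx genes, many of them in those lists too, carried a TSS peak. Families with no member in a fixed list were marked too: 33 of 45 collagen genes (Col, exact adjusted p = 6.97e-08), 42 of 73 Gpr receptor genes (2.33e-05) and 15 of 20 semaphorins (Sema, 0.000368), the last being guidance cues for axons. Solute carriers (Slc) were marked in 177 of 371 cases (47.7%, 6.65e-12). Zinc finger genes of the Zfp family were marked in 47 of 394 cases (11.9%, 7.3e-15), Rpl ribosomal protein genes in 3 of 54 and Hist histone genes in 1 of 67. None of 331 vomeronasal receptor genes (Vmn) was marked, with a 95% exact binomial interval up to 1.11%. Pcdhb protocadherins (0 of 22) and Rhox genes (0 of 34) were below by Fisher's test but not by rotation (adjusted p = 0.336 and 0.234).

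Some well known noncoding genes, picked by hand and not as a fixed list, carried the mark and others did not. Peaks covered the whole 5 kb either side of the starts of Hotair, Hottip and Hotairm1 in the Hox clusters and of Six3os1 and Dlx6os1 beside Six3 and Dlx6. Sox2ot overlaps Sox2, but its annotated start at 3:34104270 lies far from Sox2. The window at that start was covered over 22.3%. Tsix, the antisense partner of Xist, was covered over 90.4%, whereas Xist itself, Jpx, Malat1 and Neat1 had no replicated peak in that window. A peak lay at the start of 1059 of 5305 lincRNA genes (20.0%), 740 of 2958 antisense genes, 241 of 788 processed transcripts (30.6%) and 6.09% of processed pseudogenes, and these shares were not tested against protein-coding genes (29.5%). On X, 104 of 172 CpG-rich promoters were marked (60.5%) against 2989 of 8233 on the autosomes (36.3%, odds ratio 2.68, p = 2.25e-10, Fisher's exact test). This test too counts neighbouring promoters on X as independent. The median fold at these marked promoters was 4.76 on X and 6.80 on the autosomes, whereas over all replicated peaks it was 3.204 on X and 3.01 to 3.11 on the autosomes, and neither difference was tested.

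Peaks covered 12.0% of X against a median of 3.41% of the autosomes. Weak peaks near the calling threshold are argued against as the cause, since the strongest 20% of peaks alone gave a ratio of 3.21 in the lower replicate, 3.32 in the other and 3.14 in the replicated set. Gene number is argued against too, since a line over the 19 autosomes of covered share on genes per Mb put the upper 95% prediction limit for X at 4.16% (3.94% and 3.64% in the replicates). An inactive X in the female embryos of the pools remains a candidate explanation, and the test of it cannot decide: the bodies of Ddx3x, Eif2s3x, Kdm5c and Pbdc1, known to escape inactivation, were covered over 23.0% on average, and 0.396 of random sets of 4 other X genes with CpG-rich promoters were as low (median 26.7%). Among these 4 genes the values ran from 0% at Ddx3x and Eif2s3x to 72.8% at Pbdc1. The other X genes with CpG-rich promoters had a median of 7.81% and a mean of 28.4%. The mean of a set of 4 thus depends strongly on its most covered members. Kdm6a, a further escape gene left out of the test, was at 0%. None of these genes, Kdm6a included, had a replicated peak within 1 kb of the TSS. Among all X-linked protein-coding genes 42.0% had one, and among those with CpG-rich promoters 60.5%. These differences were not tested. The pools mix male and female embryos, so the sexes were not compared.

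Peaks without any overlap in the other replicate were 63407 in replicate 1 (40.9%) and 42106 in replicate 2 (31.7%), but held only 16.3% and 12.4% of the covered sequence. Of these, 71.1% in replicate 1 and 79.1% in replicate 2 were in the weaker 50% by fold enrichment, but this restates the lower overlap of weak peaks already reported, so weak peaks near the threshold stay open as a cause. Of the peaks without overlap, 75.9% and 76.2% lay within 3 kb of a peak of the other replicate, against at most 19.1% in shifted sets. Broad domains split differently by the peak caller would give such values. Weak peaks in or beside marked regions would give them too, so the values do not separate these causes. A difference in depth between the replicates also stays open, since read counts were not in the peak lists. No biological explanation was tested, as both replicates come from the same group.

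Marked forebrain progenitor TFs such as Sox2 and Otx2 had lower enrichment than regional forebrain TFs such as Nkx2-1 and Barhl1 (difference in mean log2 enrichment -1.05). A different share of CpG-rich promoters is argued against as the cause. Among CpG-rich promoters alone the difference was -1.01 (16 against 23 genes, permutation p = 1e-05, the smallest possible). CpG content was not matched within this class, so a graded effect of it stays open. The choice of the annotated start as TSS is argued against as well, since the strongest peak at any protein-coding TSS gave -1.04 (29 against 28 genes, the same p). Both permutations count neighbouring regional forebrain TFs as independent, so their p values may overstate the evidence. A hypothesis that stays open is that progenitor TFs are marked only in the cells of the dissected forebrain that do not express them, which may lower the average over cells, and no expression data or sorted cells were in the series to test it.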
